A study of Mus musculus with 8 samples.

How the data were processed

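RNA of secondary neurospheres was hybridised to Affymetrix Mouse430_2 arrays, 1 biotin-labelled sample per array, 8 arrays in all. Per the labels' protocols, forebrain cells were grown in medium with 20 ng/ml bFGF and 20 ng/ml EGF, seeded at 50000 cells/ml and collected as secondary neurospheres on day 6, and total RNA was extracted. Groups came from the titles and source names: 4 FoxO3 null and 4 wild type arrays, numbered within set 1 and set 2, with 2 arrays per set and genotype.

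The deposited values are 1 table of log2 expression values, 1 column per array. They were made with RMA, per the submitters' processing notes, a method that subtracts background, makes the arrays' distributions alike by quantile normalization and summarises the probes of a probe set. Its version is not given in the sources used here, nor whether all 8 arrays were processed together. Array medians lay between 6.27 and 6.31. RMA values compress differences of dim probe sets, and quantile normalization hides a shift shared by all genes, so every change is relative to the other genes on the array. Scanner files were not used here.

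The table has 45101 probe sets. The 64 Affymetrix control probe sets were left out, so 45037 were tested. Probe sets were named with the platform annotation: 34945 have 1 gene symbol, 932 several and 9160 none. Symbols were checked through Entrez IDs against a table of mouse genes (assembly GRCm38.p6), which changed 0 of them and gave positions for 18032 of 18193 genes. Probe sets with several symbols stood for no gene. At gene level, each gene was represented by its probe set with the highest mean over the 8 arrays.

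Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, with set as an additive term, two-sided, and Benjamini-Hochberg adjustment. A gene or probe set passed at an adjusted p under 0.05, with no limit on the fold change. Fold changes are FoxO3 null minus wild type on the log2 scale. The genotype-by-set interaction was tested in the same way. The 29 gene lists hold 651 entries, of which 601 were measured, 6 of them found through an older symbol. They cover FoxO targets, insulin signalling, the cell cycle, neural and other cell types, signalling, metabolism and stress. List genes whose probe sets carry several symbols were not analysed here. Lists were tested with camera on gene-level values with a preset correlation of 0.01, again with an estimated correlation, and with the rotation test fry. Of the 10 lists that passed, 8 also passed with fry (all but G1/S and DNA replication and autophagy and lysosome, adjusted p = 0.0572 each), which tests whether the genes of a list move one way and does not set them against other genes. Positions of passing genes were compared with Fisher's exact test.

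The genes named were fixed by rule before the data were examined: every Foxo3 probe set, the 10 genes with the largest rise and the 10 with the largest fall among those that passed with the same sign in both sets, and from each list up to 4 passing members by smallest p, or, where fewer than 2 passed, up to 2 members with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen.

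The genotype comparison and the camera test of lists were tried on simulated arrays. Each value was the fitted set mean of a probe set or gene plus independent noise of its residual SD, with 200 changed among them. For probe sets, 78 of 100 changes of 0.5 on the log2 scale and 100 of 100 changes of 1 were recovered, with 7 unchanged probe sets among 185 passing. For genes, 92 and 99 of 100 were recovered, with 13 unchanged among 204. The 1 changed list was found and 0 unchanged lists passed. The simulated noise was independent between genes and arrays, so these counts do not allow for correlated genes or technical repeats. In the real data the estimated correlation was 0.607 in the hypoxia list.

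Alternatives fixed before the data were examined covered the set term, the pairing of numbers, each set alone, quantile normalization and centring, filters on dim probe sets, the variance model, the threshold, the probe set that stands for a gene and leaving out each array in turn. Added after seeing the data were a random block or a mean for the 2 arrays of each set and genotype, and the mean of the Y-linked genes Eif2s3y, Kdm5d and Uty as a covariate. Over all probe sets the lowest correlation between arrays of a set was 0.996 and the highest between arrays of different sets 0.991, and no 2 arrays held identical columns. As a sign of RNA quality, the 3' minus 5' difference of the actin control probe sets was 0.45 ± 0.09 in wild type and 0.41 ± 0.08 in FoxO3 null arrays (log2, SD, n = 4 each, exact permutation p = 0.514, two-sided, where 0.0286 is the smallest possible), and that of Gapdh was -0.08 ± 0.02 and -0.10 ± 0.01 (exact permutation p = 0.114). Permuted within sets, an alternative chosen after seeing the data, the exact permutation p was 0.111 for actin and for Gapdh, where 0.0556 is the smallest that 36 permutations can give, so a difference in RNA quality between genotypes is not excluded. In set 1 both FoxO3 null arrays lay below both wild type arrays in each measure.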

Results

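Gene expression was measured in secondary neurospheres, free-floating balls of neural stem and progenitor cells passaged from a first generation of spheres, grown from the forebrains of FoxO3 null and wild type mice. The series asks what FoxO3, a forkhead transcription factor held out of the nucleus by insulin and growth factor signalling through Akt, does in the upkeep of adult neural stem cells. Spheres were collected on day 6 in medium with 20 ng/ml bFGF and 20 ng/ml EGF. The mice were of the FVB/N strain. The data hold 8 Affymetrix arrays, 4 per genotype, in 2 sets that each hold 2 arrays of each genotype. The labels do not say what a set is, nor whether the arrays of a set and genotype came from separate cultures or animals. P-values therefore measure only the spread between these arrays, which may be technical. Array medians lay between 6.27 and 6.31 on the log2 scale. The sets differed more than the genotypes. Principal component 1, which separated the sets, held 65.2% of the variance, and 17281 of 45037 probe sets differed between sets (limma with Benjamini-Hochberg adjustment). Set was therefore a term of every comparison of the genotypes, and the small number of arrays limits the precision.

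Foxo3 itself, on chromosome 10 from 42181845 to 42276695 (GRCm38.p6), was lower in the FoxO3 null arrays in both of its brightest probe sets. Probe set 1434831_a_at averaged 10.20 ± 0.14 in wild type and 9.03 ± 0.12 in FoxO3 null arrays (log2, SD, n = 4 each). It fell by 1.17 (limma adjusted p = 0.000649), which left 44.5% of the wild type signal. Probe set 1434832_at fell by 1.07 (adjusted p = 0.0021), leaving 47.8%. Another probe set, 1444226_at, which the annotation gives to Foxo3 and another gene, fell by 0.48 (adjusted p = 0.0207). In these 3 probe sets each FoxO3 null array lay below each wild type array. With no set term 1 of the 3 passed. The dim probe set 1450236_at had a log2 fold change of 0.33 ± 0.08 (SE) and did not pass (adjusted p = 0.11), but it passed without wild type array 1_2 (adjusted p = 0.0421). The labels do not say which part of the gene is deleted, and a probe set outside that part checks nothing about the genotype.

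**Figure D1:**
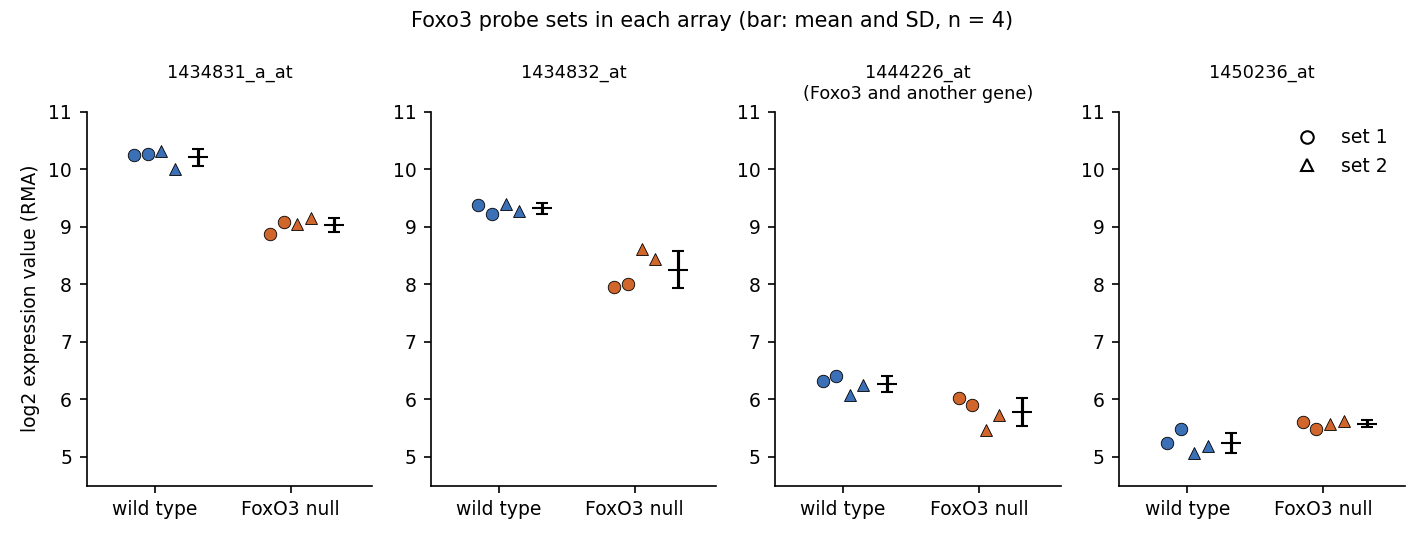
Log2 expression value of each Foxo3 probe set (y axis) in the wild type and FoxO3 null arrays (x axis), with circles for set 1, triangles for set 2, and the mean and SD of the 4 arrays beside them. In 1434831_a_at the FoxO3 null arrays lie around 9.03 and the wild type arrays around 10.20.

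Among the genes that passed, more were lower than higher in FoxO3 null spheres, while the median log2 fold change of all genes was 0.0091. Of 18193 genes, 291 passed the test, 213 lower and 78 higher in FoxO3 null arrays, with median changes of 1.33-fold down and 1.29-fold up. The changes were small: 58 of the 291 reached 1.5-fold and 7 reached 2-fold. All 291 had the same sign in both sets, which selection by a fit over both sets favours. Over all genes 57.3% had the same sign. The share of lower genes depended on the fit: 457 of 796 with a random block of set and genotype together, 370 of 604 with a variance trend, 289 of 456 above the median level and 4 of 8 with the mean of the Y-linked genes as a covariate were lower. The largest rises among them were in Prl, which encodes the pituitary hormone prolactin (log2 fold change 1.16 ± 0.17 (SE), adjusted p = 0.0086), and Ccn2, a matricellular growth factor (1.06 ± 0.10, adjusted p = 0.00146). Next came Capn6, a calpain family member (1.03 ± 0.15), and Prdm1, a transcriptional repressor (1.00 ± 0.11, adjusted p = 0.00299). Soga3, Myl9, a myosin light chain of smooth muscle, Clic5, a chloride channel family member, Dact1, a regulator of Wnt signalling, Cyp1b1, a cytochrome P450, and Tpd52l1 rose by 0.61 to 0.90. Of these largest rises, Ccn2, Prdm1, Soga3 and Tpd52l1 lie within 20 megabases of Foxo3, where alleles carried along with the null allele stay an open explanation. The rise of Soga3 differed between sets, from 0.34 in set 1 to 1.46 in set 2 (gene-level interaction adjusted p = 0.0293), but it did not pass the interaction test over all probe sets.

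The largest falls among genes that passed, after Foxo3, were in Slc2a3, the neuronal glucose transporter (log2 fold change -1.03 ± 0.16 (SE), adjusted p = 0.0141), and Prss35, a serine protease family member, which kept 0.499 of its wild type value. They went on with Six3 and Otx2, homeobox genes of forebrain development (-0.95 ± 0.09 and -0.93 ± 0.10), and Gad1, the enzyme that makes GABA (-0.91 ± 0.09, adjusted p = 0.0015). Ddit4, a stress-induced inhibitor of mTORC1, fell by 0.90 ± 0.12, and Afap1l2, Prelid2 and Tafa2 fell by 0.84 to 0.87. Ddit4 also lies within 20 megabases of Foxo3. Of 45037 single probe sets 361 passed, 264 lower and 97 higher in FoxO3 null arrays. Among the 179 passing genes that have over 1 probe set, another probe set passed in the same direction in 47, and 0 genes had probe sets passing in both directions. The number of genes depended on the fit: 3 passed with no set term, 63 in set 1 alone, 171 in set 2 alone, 133 with a replicate block, 89 with set as a random block and 8 with the mean of the Y-linked genes as a covariate, which left 290 of the 291 in their direction. With the mean of the 2 arrays of each set and genotype, which allows for technical repeats, limma passed 0 genes, and without moderation of the variance 0 passed too (1805 and 2530 at an unadjusted p under 0.05). Without 1 array the number was 117 (wild type 1_1), 104 (wild type 2_1), 188, 193, 186 and 136 (FoxO3 null 1_1, 1_2, 2_1 and 2_2). Of 57 named genes that passed, 14 to 31 missed the threshold in such a fit. All 57 missed it with array means and with no moderation, 56 with no set term, and with the Y-linked covariate 55 missed it and 1 turned its sign. In the test of all probe sets, 84 of the 291 genes had no passing probe set, among them the named genes Soga3, Myl9, Tafa2, Nes, Hey2, Pfkfb3, Pgam1, Aldoa, Trib3 and Eif2s3y.

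**Figure D2:**
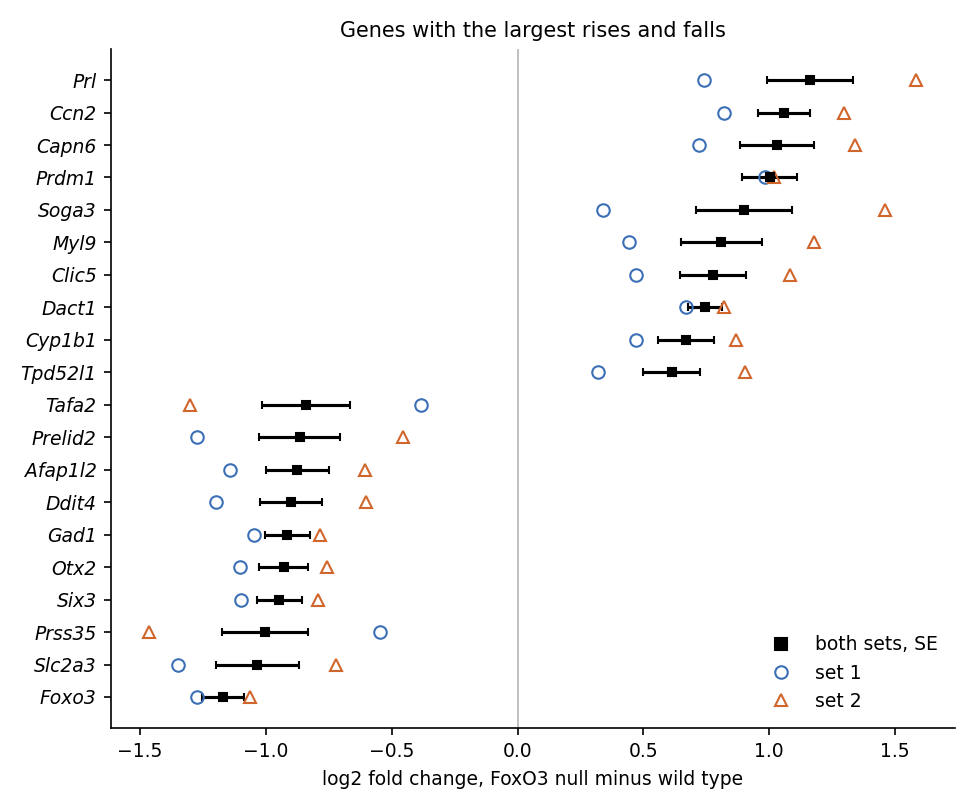
Log2 fold change, FoxO3 null minus wild type (x axis), of the 10 genes with the largest rises and the 10 with the largest falls (y axis), with the SE of the fit over 8 arrays and the value in set 1 (circles) and set 2 (triangles). Every gene shown has the same sign in both sets, as the rule for naming required, from Prl at 1.16 to Foxo3 at -1.17.

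To place these changes, 29 gene lists fixed before the data were examined were tested with camera, which sets a list against all other genes. With a preset correlation between genes 10 lists passed, 8 lower and 2 higher in FoxO3 null arrays. With a correlation estimated from the data 0 passed in camera, and the estimated-correlation p is given beside each list. Another split of the 8 arrays into 4 and 4 gave 12 lists; among the 18 splits that hold 2 arrays of each set on both sides, the highest other count was 9.

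Known FoxO target genes were lower on balance. Of 36 measured, 7 fell and 0 rose (14 and 1 when adjusted over the list alone), and 28 had a negative fold change. The median log2 fold change was -0.12 (camera adjusted p = 1.38e-08, and adjusted p = 0.207 with an estimated correlation). With the mean of the Y-linked genes as a covariate it was -0.04 (adjusted p = 0.00263). Igf1r and Insr, the IGF1 and insulin receptors, fell by 0.42 ± 0.05 and 0.35 ± 0.06 (SE). Ccng2, an atypical cyclin linked to cell cycle exit, fell by 0.49 ± 0.09, and Ddit4 by 0.90. Pdk4, which restrains pyruvate entry into mitochondria, and Txnip, an inhibitor of thioredoxin, both chosen after their values were seen, fell by 0.76 and 0.59. The list median was -0.11 in set 1 and -0.15 in set 2. In the insulin, IGF and PI3K-Akt pathway list, Igf1r, Insr and Igfbp5, an IGF binding protein (-0.47 ± 0.08), fell among 24 measured genes (3 higher and 5 lower when adjusted over the list alone). The list as a whole did not pass: its median was 0.01, its mean -0.02 and its camera adjusted p 0.753. For Igf1r, 1 of 5 probe sets passed in the test of all probe sets, and the probe set of Insr with the largest variance gave 0.03 (adjusted p = 0.889).

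Among the lists that passed, hypoxia-inducible genes and enzymes of glycolysis had the largest median shifts. Of 27 hypoxia and HIF target genes, 11 fell and 0 rose, 25 had a negative fold change, and 24 fell when adjusted over the list alone. The median log2 fold change was -0.49 (camera adjusted p = 6.96e-24, and adjusted p = 0.207 with an estimated correlation). Besides Slc2a3 and Ddit4, the falls took in Car12, a carbonic anhydrase (-0.68 ± 0.07 (SE)), and Mxi1, an antagonist of Myc (-0.50 ± 0.05). Among them too were Slc2a1, the widely expressed glucose transporter (-0.67 ± 0.08), and Adm, the vasodilator peptide adrenomedullin (-0.55 ± 0.07). Vegfa, the vascular growth factor, chosen after its value was seen, fell by 0.84. Of 17 glycolysis genes, 4 fell: Slc2a1, Pfkfb3, which makes the activator of phosphofructokinase (-0.52 ± 0.10), Pgam1 (-0.24 ± 0.05) and Aldoa (-0.26 ± 0.05). Slc2a1 and Pfkfb3 are members of the hypoxia list as well. Adjusted over the list alone, 13 glycolysis genes fell and 1 rose; the median was -0.26 (camera adjusted p = 3.32e-11, and adjusted p = 0.207 with an estimated correlation).

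Both shifts were present in each set and larger in set 1: the hypoxia median was -0.69 in set 1 and -0.36 in set 2, and the glycolysis median -0.32 and -0.16 (camera of the interaction, chosen after the data were seen, adjusted p = 1.27e-06 and 0.000193, and 0 of 29 lists with an estimated correlation). With the mean of the Y-linked genes as a covariate the medians were -0.70 and -0.32, and both lists passed. In set 1 the actin and Gapdh 3' minus 5' differences, signs of RNA quality, were also lower in both FoxO3 null arrays than in both wild type arrays. Over both sets together, genes of neighbouring pathways did not shift as groups. Oxidative phosphorylation had 0 of 24 genes passing (median 0.01, camera adjusted p = 0.865). The pentose phosphate, glutamine and serine list had 0 of 20 (median 0.04, adjusted p = 0.672). There the amino acid transporter Slc38a2 had a log2 fold change of -0.29 (adjusted p = 0.0795) and fell when adjusted over the list alone. Cholesterol synthesis had 0 of 17 genes passing over both sets (median 0.0059, camera adjusted p = 0.753). In each set alone this list passed, in opposite directions: lower in set 1 (median -0.09, camera adjusted p = 0.00724) and higher in set 2 (0.12, adjusted p = 0.000789). The interaction adjusted p was 1.03e-06 (0.496 with an estimated correlation), and with the Y-linked covariate the median was -0.18 (camera adjusted p = 4.83e-07).

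**Figure D3:**
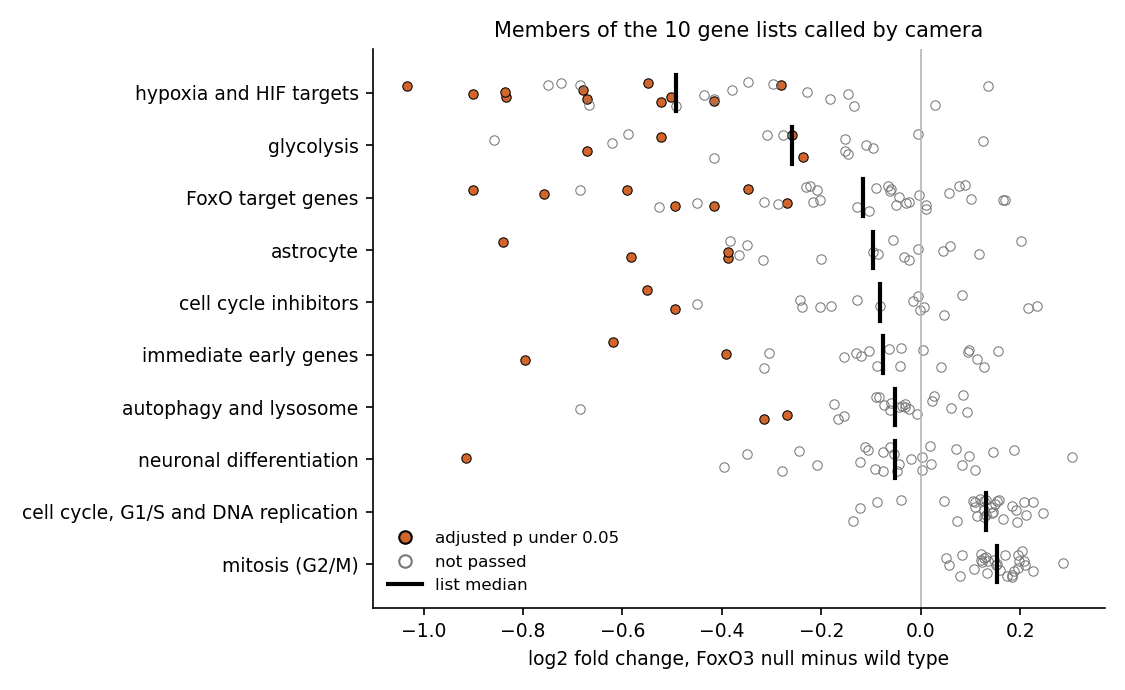
Log2 fold change, FoxO3 null minus wild type (x axis), of each measured member of the 10 gene lists that passed with the preset correlation (y axis), filled where the gene passed over all genes, with a bar at the list median. The hypoxia and glycolysis medians lie at -0.49 and -0.26, and the mitosis and G1/S medians at 0.15 and 0.13.

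Cell cycle genes were slightly higher in FoxO3 null spheres as a group, with no mitosis or G1/S gene passing over all genes. All 29 measured mitosis genes had a positive fold change, with a median log2 fold change of 0.15 (camera adjusted p = 1.72e-12, and adjusted p = 0.222 with an estimated correlation), and 14 rose when adjusted over the list alone. The smallest p-values were those of Nek2, a centrosomal kinase (0.23 ± 0.05 (SE), adjusted p = 0.0647), and Kif23, a kinesin of cytokinesis (0.29 ± 0.07, adjusted p = 0.0683). Of 30 G1/S and DNA replication genes, 26 had a positive fold change (0 passed over all genes and 0 when adjusted over the list alone, median 0.13, camera adjusted p = 2.82e-06, and adjusted p = 0.304 with an estimated correlation), and the smallest p-values were at Uhrf1 with 0.23 and Mcm4, a subunit of the replicative helicase, with 0.18. Among 17 cell cycle inhibitors, Cdkn2b, which encodes the CDK4/6 inhibitor p15, fell by 0.55 ± 0.07, and Ccng2 by 0.49. The list median of the inhibitors was -0.08, and 5 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00297, and adjusted p = 0.207 with an estimated correlation). In set 1 the G1/S list did not pass (median 0.04, camera adjusted p = 0.171) and in set 2 it did (0.21, adjusted p = 1.30e-08), with an interaction adjusted p of 8.52e-05 (0.496 with an estimated correlation). Y-linked genes were lower in the same FoxO3 null arrays (Eif2s3y, log2 fold change -0.64 ± 0.13). With their mean as a covariate the median was 0.04 for mitosis (camera adjusted p = 0.474), -0.0047 for G1/S (adjusted p = 0.864) and -0.05 for the inhibitors (adjusted p = 0.131). That mean itself correlates with genotype within sets (r = -0.861), so this fit cannot tell a share of male cells from the genotype.

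Markers of neural stem and progenitor cells went both ways. Nes, the intermediate filament nestin, rose by 0.29 ± 0.06 (SE), and Hopx, a homeodomain protein of quiescent stem cells, rose by 0.39 ± 0.08. Id2, an inhibitor of differentiation, fell by 0.64 ± 0.10, and the other 21 of 24 genes did not pass (3 higher and 5 lower when adjusted over the list alone, median -0.03, camera adjusted p = 0.753). For Nes, 0 of 3 probe sets passed in the test of all probe sets. In the neuronal list Gad1 fell and 27 of 28 genes did not pass. Snap25, a synaptic protein, had a log2 fold change of -0.35 (adjusted p = 0.0692) and Gap43, a growth cone protein, -0.40 (adjusted p = 0.0726). The neuronal list was lower as a whole (median -0.05, 2 higher and 6 lower when adjusted over the list alone, camera adjusted p = 0.023, and adjusted p = 0.207 with an estimated correlation). It did not pass in set 2 alone (adjusted p = 0.201) nor without wild type array 1_1 (adjusted p = 0.0725).

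Glial genes fell in part. Of 19 astrocyte genes, 4 fell: Slc1a2, the main glutamate transporter of astrocytes, by 0.84 ± 0.05 (SE; adjusted p = 0.000279), and Ntsr2, a neurotensin receptor, by 0.58 ± 0.08. Fgfr3, an FGF receptor, fell by 0.39 ± 0.06, and Apoe, the lipid carrier apolipoprotein E, by 0.39 ± 0.07. The astrocyte median was -0.10, with 6 genes lower when adjusted over the list alone (camera adjusted p = 1.93e-05, and adjusted p = 0.207 with an estimated correlation). For Slc1a2 1 of 5 probe sets passed. The astrocyte list did not pass in set 1 alone (median -0.03, adjusted p = 0.0648, interaction adjusted p = 0.00579, and 0.496 with an estimated correlation) nor with the Y-linked mean as a covariate (-0.0018, adjusted p = 0.703), and Y-linked genes were lower in the same arrays. As this covariate correlates with genotype within sets (r = -0.861), the lost call does not show a cause. In the oligodendrocyte lineage list, 4 of 21 genes fell, among them the progenitor markers Pdgfra (-0.67 ± 0.09), Cspg4, which encodes NG2 (-0.56 ± 0.08), and Gpr17 (-0.66 ± 0.11), and the lineage factor Sox10 (-0.27 ± 0.05). As a group the oligodendrocyte list did not pass, and its other members went both ways (median 0.05, mean -0.0050, camera adjusted p = 0.753, 2 higher and 4 lower when adjusted over the list alone). With the Y-linked mean as a covariate the list passed as higher (median 0.09, camera adjusted p = 0.00871).

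Signalling and stress genes changed in small numbers. In the list of Notch, Wnt, Hedgehog and BMP pathway genes, Dll3, a Notch ligand family member (-0.37 ± 0.06 (SE)), Lgr5, an R-spondin receptor (-0.58 ± 0.10), and the Notch effectors Hey1 (-0.29 ± 0.05) and Hey2 (-0.28 ± 0.06) fell among 30 genes. Adjusted over the list alone, 7 fell, and the list did not pass (median 0.0043, mean -0.05, camera adjusted p = 0.17), though it passed as lower in set 1 alone (adjusted p = 0.0168; interaction adjusted p = 0.41) and without wild type array 2_2. Hey2 was dim, at 4.62 in wild type and 4.34 in FoxO3 null arrays. Among 20 immediate early genes, Fosl2 (-0.80 ± 0.10), Ier3 (-0.62 ± 0.08) and Jun (-0.39 ± 0.07) fell. Adjusted over the list alone, 6 fell, and the list median was -0.08 (camera adjusted p = 0.00201, and adjusted p = 0.207 with an estimated correlation). Of 22 autophagy and lysosome genes, Wipi1 (-0.32 ± 0.05) and Gabarapl1 (-0.27 ± 0.05), both autophagosome proteins, fell. Adjusted over the list alone, 3 fell, and the list median was -0.05 (camera adjusted p = 0.00329, and adjusted p = 0.329 with an estimated correlation). With the Y-linked mean as a covariate, which correlates with genotype within sets (r = -0.861), both of these lists lost their call. Their medians there were -0.10 for immediate early genes (camera adjusted p = 0.396) and 0.02 for autophagy and lysosome genes (adjusted p = 0.607). The autophagy list did not pass in set 1 alone (camera adjusted p = 0.0648).

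Ddit3 and Trib3, genes induced by amino acid and unfolded protein stress, fell by 0.38 ± 0.07 and 0.32 ± 0.06 (SE), and 21 of 23 genes of that list did not pass (median 0.0087, mean -0.02, camera adjusted p = 0.753). In set 1 alone this list passed as lower (median -0.04, adjusted p = 0.0193), and in set 2 its median was 0.08 (interaction adjusted p = 0.00356, and 0.496 with an estimated correlation). In the antioxidant list 0 of 26 genes passed over all genes (2 higher and 2 lower when adjusted over the list alone, median 0.02, camera adjusted p = 0.904): Nqo1, a quinone reductase, stood at 0.35 (adjusted p = 0.0514) and Mt2, a metallothionein, at -0.24 (adjusted p = 0.0558). The apoptosis list (0 of 22, median 0.04, adjusted p = 0.753), with Bcl2 at 0.19 and Mcl1 at 0.13, and the p53 list (0 of 23, median 0.0089, mean -0.01, adjusted p = 0.865, 1 lower when adjusted over the list alone), with Sesn1, a stress-induced sestrin, at -0.32 and Brca1 at 0.18, did not pass. For Sesn1, 2 of 4 probe sets passed as lower in the test of all probe sets. The same held for the interferon list (0 of 23, median -0.02, mean 0.0039, adjusted p = 0.753), with Ifi27 at 0.32, and the ribosomal protein list (0 of 14, median -0.0090, adjusted p = 0.826), with Rps6 at 0.07.

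Markers of other cell types that a sphere culture could hold gave no list that passed. Median log2 fold changes were 0.02 for microglia and macrophages (0 of 14 genes), 0.03 for endothelial cells (0 of 13), -0.0022 for pericytes, meninges and fibroblasts (0 of 14, mean 0.08) and -0.04 for red blood cells (0 of 4), each with a camera adjusted p of 0.753. Acta2, smooth muscle actin, had a log2 fold change of 0.48 (adjusted p = 0.135). In the ependymal and choroid plexus list Otx2 fell among 14 genes (median 0.01, mean -0.03, camera adjusted p = 0.958), and Foxj1, the master factor of motile cilia, stood at 0.12. Genes of the sex chromosomes did differ: Xist, the RNA that silences an X chromosome in female cells, rose by 0.44 ± 0.08 (SE). The Y-linked Eif2s3y fell by 0.64 ± 0.13 and Uty fell by 0.42 ± 0.08, so that 3 of the 5 measured genes passed (1 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.0571 for the list). The list passed in 5 of the 8 fits that left out 1 array, those without wild type 1_2 or 2_2 or FoxO3 null 1_2, 2_1 or 2_2. Eif2s3y stood at 9.09 ± 0.16 (SD) in wild type and 8.44 ± 0.41 in FoxO3 null arrays, and its fall was 0.35 in set 1 and 0.93 in set 2.

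Set 1 and set 2, which share no array, gave partly the same genotype changes. Across all 18193 genes, which are not independent replicates, the log2 fold changes of the sets correlated with a Pearson r of 0.297 (Spearman rho 0.221) and had the same sign in 57.3%. Among the 9096 genes above the median level r was 0.397. The genotype effect itself differed between sets in 31 probe sets (limma interaction, adjusted for 45037 tests). The smallest p-values, chosen after they were seen, were those of both probe sets of Pomc, the precursor of ACTH and melanocortins. Probe set 1433800_a_at had a log2 fold change of 0.04 in set 1 and 2.71 in set 2 (interaction adjusted p = 0.000221). Among the other probe sets, Zic1, Tagln and Lgi1 are given as examples chosen after their values were seen. Zic1, a zinc finger factor of the dorsal neural tube, in probe set 1439627_at, went from -0.39 in set 1 to 1.73 in set 2 (adjusted p = 0.00707), and Tagln, a smooth muscle protein, from -0.45 to 1.48 (adjusted p = 0.0146). Lgi1, a secreted neuronal protein, went from 0.02 to -1.49 (adjusted p = 0.00283).

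**Figure D4:**
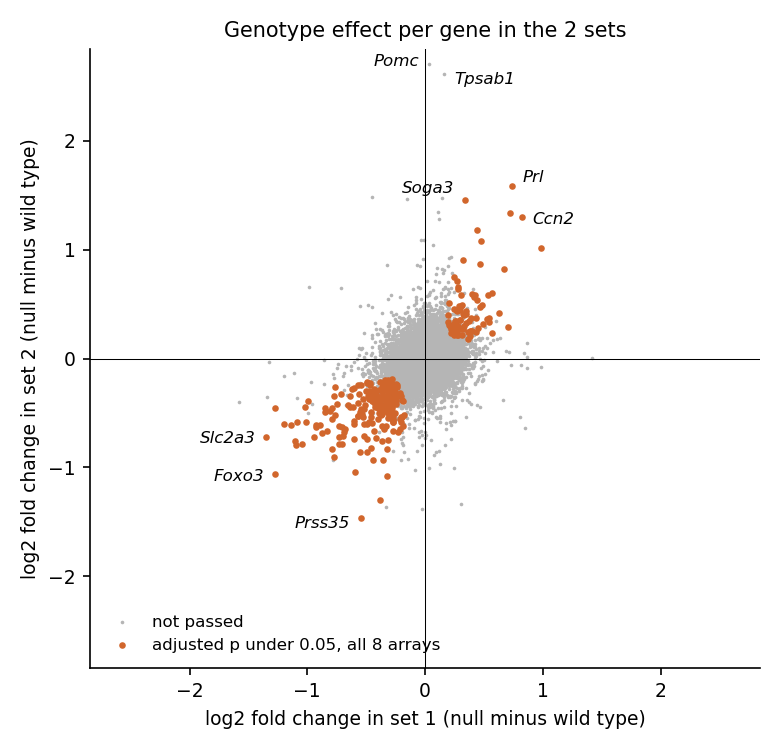
Log2 fold change, FoxO3 null minus wild type, of each of the 18193 genes in set 1 (x axis) and set 2 (y axis), with the 291 genes that passed over all 8 arrays in colour. The coloured genes, which were selected over both sets, lie in the quadrants of equal sign, and Pomc stands at 0.04 in set 1 and 2.71 in set 2.

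Genes on chromosome 10, which carries Foxo3, passed more often than genes elsewhere. Leaving out Foxo3, 24 of 859 genes on this chromosome passed (2.79%) against 265 of 17172 on the others (1.54%; odds ratio 1.83, 95% confidence interval 1.15 to 2.81, Fisher's exact test, two-sided, p = 0.00768). Within 20 megabases of Foxo3, 9 of 200 genes passed (odds ratio 2.95, interval 1.32 to 5.81, Fisher's exact p = 0.00507): Prdm1, Frk, Tpd52l1, Soga3 and Ccn2 were higher, and Hddc2, Hey2, P4ha1 and Ddit4 lower. The nearest of these was Prdm1 (44437174 to 44528558), 2.16 megabases from Foxo3. Sesn1 (41810574 to 41908436) lies nearer and did not pass as a gene (adjusted p = 0.0565), but 2 of its 4 probe sets passed in the test of all probe sets. Ddit4 is at 59949675 to 59951770, 17.7 megabases away. Taken by direction within 20 megabases, the odds ratio was 6.24 for higher genes (interval 1.94 to 15.5, Fisher's exact p = 0.00175). For lower genes it was 1.74 (interval 0.464 to 4.59, Fisher's exact p = 0.301). On the rest of chromosome 10, 15 of 659 genes passed (2.28%, odds ratio 1.45, interval 0.798 to 2.46), and on the X chromosome 10 of 617 (odds ratio 1.01).

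**Figure D5:**
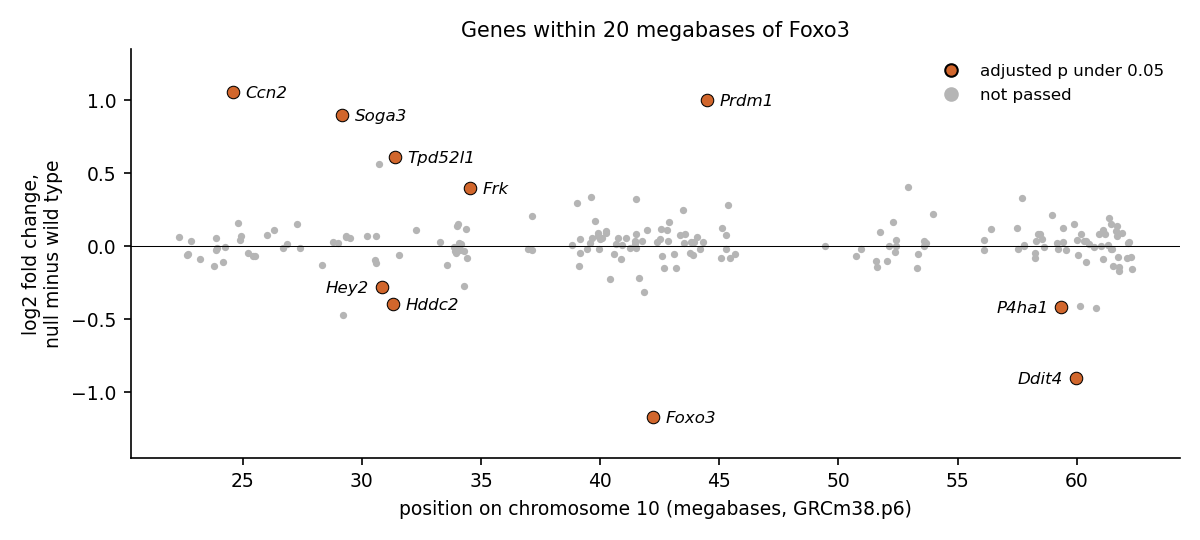
Log2 fold change, FoxO3 null minus wild type (y axis), of the genes within 20 megabases of Foxo3 by position on chromosome 10 in megabases (x axis), in colour where the gene passed. Foxo3 lies at -1.17, Prdm1 at 1.00 and Ddit4 at -0.90.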

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

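The tests of pituitary cells, of male cells, of oxygen and density, of carried-along alleles, of the probe sets that did not prompt the question and of differences between sets in gene lists were chosen after the results were seen; the others were fixed before.

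The genotype effect differed between sets in 31 probe sets, by a test of the interaction. Among them were both probe sets of Pomc and a probe set of Gh, growth hormone; Prl, the largest rise among genes that passed, was 0.74 in set 1 and 1.58 in set 2. The 7 probe sets of Pomc, Gh and Prl were each higher in both FoxO3 null arrays than in both wild type arrays of set 2 (7 of 7). Of these, 4 prompted the question and cannot test it, among them both probe sets of Pomc (2.71 and 2.75 in set 2) and that of Prl. The other 3, all of Gh, were higher as well, which argues against a fault of single probe sets for Gh only. For Pomc and Prl no independent probe set tests it. In set 2 Pomc stood at 11.33 and 11.34 in FoxO3 null arrays against 8.49 and 8.77 in wild type. Pituitary cells or RNA in these cultures remain a candidate explanation: the 14 other measured pituitary genes, of which neurons express some, such as Chgb and Scg2, gave a camera p of 0.463 in set 2, with 8 of 14 higher and a median of 0.01, and among the pituitary hormone subunits Cga was 0.32 higher and Lhb -0.24. Scg2 stood at 0.48, Chgb at 0.39 and Pcsk1 at -0.20 in set 2. Several of the 14 genes are dim, such as Lhb (5.73 in wild type) and Fshb (4.56), so this test could hardly respond. Neural expression of Pomc in FoxO3 null cells of set 2 alone stays open too, as untested. The labels do not say what differs between the sets and name no sort by cell type. As the other pituitary genes were dim in part and went both ways, these explanations cannot be told apart.

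The fall of hypoxia and glycolysis genes is the group a follow-up would start from. A shift of all genes of like brightness was not seen: 0 of 10000 random lists matched on mean level had a median as low as -0.49, the lowest being -0.08. Quantile normalization largely removes such a shift beforehand, so this test could hardly have come out otherwise and lends the fall no support. RNA quality, whose signs separated the genotypes in set 1, where the fall was larger, was not tested as a cause. A smaller share of male cells, read from the Y-linked genes, was tested in 2 ways. The initial test left it open: the fall in set 2 was smaller than the Y-linked ratio of 2.73 would give, but by 1.42 standard errors. The other test was put in its place, and its bound set, after both results were seen, so it cannot decide the question. With the Y-linked mean as a covariate the mean change of the 40 genes of both lists was -0.65 ± 0.17 (SE). That is -3.78 standard errors from 0, against -0.41 ± 0.10 without the covariate, which itself correlates with genotype within sets (r = -0.861). A smaller share of male cells stays open. Oxygen or cell density that differed between the cultures could give the same picture, with 25 of 27 hypoxia genes lower, and since the labels give no such record for single cultures it cannot be told apart from the genotype. An effect of FoxO3 on these genes stays a hypothesis.

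Genes within 20 megabases of Foxo3 passed more often than others. Chance clustering is argued against, since 0.598% of 13380 overlapping windows of 200 neighbouring genes on other chromosomes held as many passing genes as the 9 found here. Alleles of another strain carried along with the null allele would concentrate passing genes near Foxo3 more than on the rest of the chromosome: the odds ratio for that was 2.02 (interval 0.767 to 5.02, Fisher's exact p = 0.137), which leaves it open, as the genes are too few. FoxO target, hypoxia and glycolysis genes that lie there, such as Ddit4, do not account for it clearly either way: without the members of these lists the odds ratio was 2.46 (interval 0.968 to 5.25, Fisher's exact p = 0.029).

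Of 184 groups of 4 arrays tested, 5 had an array far from the others. The usual chance rate of about 1 in 20 is for 4 values of one kind, and since each group holds 2 arrays of each set it cannot be used here. Insr in FoxO3 null array 1_2 was 8.53 against 8.45 to 8.46 in the others (gap over range 0.870). Slc2a1 in wild type array 1_2 was 11.16 against 11.40 to 11.43 (0.884), and Ier3 in the same array was 9.96 against 10.11 to 10.13 (0.858). Acta2 in FoxO3 null array 2_1 was 10.92 against 10.69 to 10.70 (0.951). Rps6 in FoxO3 null array 2_2 was 10.29 against 10.34 to 10.35 (0.839).

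The rise of Soga3 was larger in set 2 by 1.12 (gene-level interaction adjusted p = 0.0293), though its probe set was not among those that passed the interaction over all probe sets. For gene lists, the set 2 minus set 1 difference of the genotype effect passed in 11 of 29 lists with the preset correlation, and in 0 with an estimated correlation (lowest adjusted p = 0.496). The median differences were 0.23 for hypoxia and HIF targets, 0.12 for glycolysis, 0.19 for cholesterol synthesis, 0.13 for G1/S, 0.11 for mitosis, 0.10 for unfolded protein and amino acid stress, 0.090 for the pentose phosphate, glutamine and serine list and 0.046 for pericytes, meninges and fibroblasts. They were -0.12 for the oligodendrocyte lineage, -0.11 for astrocytes and -0.13 for p53 targets.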

How the results depend on the processing

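The random block of set and genotype together, the mean of the 2 arrays and the Y-linked covariate were chosen after seeing the data; the cause of a move was not tested except where stated. With fewer arrays or values (set 1 alone, set 2 alone, array means, an array left out) the test has less to work with. The probe set count of 361 became 3 with no set term, 138 with the pairs of set and number as a replicate block, 63 with set as a random block, 42 in set 1, 146 in set 2, 827 with a variance trend and robust estimation, 0 with no moderation of the variance, 1354 with set and genotype together as a random block (whose estimated correlation was negative, -0.264), 39 with array means, 0 with the Y-linked covariate, 88 with a fold of at least 1.5 and 714 at an adjusted p under 0.10; without 1 array it ranged from 83 to 271. The gene count of 291 became, in that order, 3, 133, 89, 63, 171, 604, 0, 796, 0, 8, 58 and 541, was 456 above the median level, and ranged from 104 to 222. Where limma passed 0 genes, 2530 (no moderation) and 1805 (array means) had an unadjusted p under 0.05. With the Y-linked covariate, which correlates with genotype within sets (r = -0.861), standard errors grew by 1.93 times and fold changes kept 0.886 of their size, with 1365 genes at an unadjusted p under 0.05. Of the 291 genes, 290 kept their direction there and with the probe set of largest variance, and 291 in each other alternative that tested all of them. The balanced design gives the same fold change with no set term, blocks, array means, a variance trend or no moderation. Signs could not turn there. The other fits share arrays with the fit that selected the genes, so a kept sign is no independent support. Numbers did not pair arrays within a set (r = 0.07 in set 1 and -0.06 in set 2), so the block is only a check; it shared 125 genes with the 291 and changed no list call. Of 3 Foxo3 probe sets 1 passed with no set term. Gene lists went from 10 to 0 with an estimated correlation and ranged from 9 to 12 without 1 array. With the Y-linked covariate 8 passed, among them 4 of the 10, all as lower. The oligodendrocyte and p53 lists passed there as higher (medians 0.09 and 0.13), and the unfolded protein and cholesterol lists as lower (-0.08 and -0.18). Camera takes no random block, so that alternative was not run for lists. The interaction count of 31 was 52 at an adjusted p under 0.10. The correlation of 0.297 between sets was 0.397 above the median level, 0.845 among passing genes, which were selected on both sets, and 0.216 to 0.323 without 1 array. Among named genes and lists that passed, signs turned for Insr with the probe set of largest variance (0.033), and with the Y-linked covariate for Eif2s3y (0.018), which is part of that covariate, and for the medians of the G1/S list (-0.0047) and the autophagy list (0.020). The number of arrays and the compression of dim signals near background limit what could pass.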

Other observations

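The lists of circadian and X-linked genes were drawn up after the main results were seen, and the rule for judging other splits of the arrays was reworded after its counts were seen, while the other tests were fixed before their own results.

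Dbp, a transcription factor driven by the circadian clock, was lower in FoxO3 null arrays in both sets, at -0.70 in set 1 and -0.72 in set 2 (log2 fold change -0.71 ± 0.12 (SE), limma adjusted p = 0.0207). Per3, a clock component, stood at -0.32 ± 0.07 (adjusted p = 0.06) and Nr1d1, a clock repressor, at -0.14 (adjusted p = 0.4). Of the 9 other circadian output genes 8 had a negative fold change, with a median of -0.09. Tef, Per2 and Bhlhe41 changed sign between the sets. As a group the 9 genes gave an unadjusted p of 0.0105 in limma's camera with the preset correlation, as predicted for a difference in clock phase between the cultures. The test was not run with an estimated correlation, which kept 0 of the 10 list calls, so it cannot decide this hypothesis. A direct effect of FoxO3 on Dbp was not tested.

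Genes on the X chromosome that escape silencing did not pass: Eif2s3x stood at 0.21 ± 0.05 (SE, adjusted p = 0.0909), Kdm6a at 0.14, Ddx3x at 0.08 and Kdm5c at -0.11. Eif2s3y lay between 7.94 and 9.24 and Xist between 10.69 and 12.62 over the arrays, while Kdm5d in FoxO3 null array 2_1 and Uty in FoxO3 null array 2_2 were at 6.24, under those arrays' medians.

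The FoxO target and hypoxia lists share 2 genes. Without them the 34 remaining FoxO target genes still gave a camera p of 7.34e-08 with the preset correlation and a median of -0.10. That argues against the shared members as the whole cause of that call, which is itself lost with an estimated correlation (adjusted p = 0.207 for the full list). Other lists that passed overlap too, so their calls are not separate findings. The hypoxia and glycolysis lists share Slc2a1, Pfkfb3, Hk2 and Ldha. FoxO targets share Cdkn1a, Cdkn1b, Ccng2 and Rbl2 with the cell cycle inhibitors, and Atg12, Map1lc3b, Gabarapl1 and Bnip3 with the autophagy list.

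Other splits of the 8 arrays into 4 and 4, each fitted with the set term, were compared with the real one. The split that equals the sets cannot be fitted with that term, which leaves 34. For probe sets, 1 of 34 splits, the real one, gave 361, and the highest of the others gave 0. For genes, 1 of 34 gave 291, and the highest of the others gave 4. The labels do not say whether the arrays of a set and genotype are independent samples. The 18 splits that are balanced over the sets like the real one are too few for a share under 0.05, and the highest of the others among them gave 0 probe sets and 4 genes. For gene lists, 2 of 34 splits gave at least the real 10, and the highest of the others gave 12, so chance cannot be excluded for the number of lists called with the preset correlation. Among the 18 balanced splits the highest other count of lists was 9. An earlier wording of the rule left the real split out of that count and would have excluded chance for the lists. Without the set term, the split that follows the sets gave 15950 probe sets and 7296 genes, which points to the sets as the main structure of the samples.

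Of the 64 control probe sets, 0 passed for genotype in limma, and 7 had an unadjusted p under 0.05. These 7 were all higher in FoxO3 null arrays, by 0.21 to 0.27 on the log2 scale. They are probe sets of 18S ribosomal RNA and of the Thr, Phe and Dap controls, which are not mouse genes. The cause was not tested, and a technical difference between the genotypes is not excluded.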
